A study of Mus musculus and Homo sapiens with 22 samples.

How the data were processed

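B cell populations from healthy human donors and C57BL/6J mice were profiled by bulk RNA sequencing of Smart-seq2 libraries. The human part held 9 libraries, 3 each from combined transitional 1 and 2 (T1/T2), transitional 3 (T3) and follicular (FO) B cells of 3 donors. The mouse part held 13 libraries, 3 each from T1, T2 and T3 cells and 4 from FO cells. Per the submitters' processing notes, the authors made FASTQ files with bcl2fastq, checked them with FastQC and counted with RSEM against hg38 or mm10 with Ensembl genes. The versions of these tools and the annotation release are not given in the sources used here, nor are the sorting gates, cell numbers or library preparation dates. The deposited tables, 1 per species, hold RSEM expected counts per gene and library. The human file lists 60675 genes and the mouse file lists 46983. The columns were joined to samples by title, and 0 columns of either table were left without a sample.

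Groups were taken from the sample titles and source names. In 6 of 9 mouse transitional samples the cell type tag differs from both, and that tag was not used. Replicate numbers in the titles were read as donor or mouse numbers. Across residual log CPM after removal of group means, human libraries of the same number had a median Pearson r of 0.373 (0.125 to 0.562, 9 pairs) and libraries of different numbers -0.404 to 0.118 (18 pairs). In mouse the same-number median was 0.0112 (-0.0233 to 0.0928, 18 pairs). As set before the data were seen, the number was tried as a block beside the group-only fit.

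Expected counts were rounded to whole numbers. Genes passed edgeR filterByExpr by group (count minimum 10, total minimum 15), leaving 12779 human and 9392 mouse genes. With R 4.3.3, counts were scaled with TMM and fitted with edgeR 4.0.16 (quasi-likelihood, robust, all groups of a species in 1 fit), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Every adjusted p printed for a gene is from this edgeR test unless another tool is named. CPM values (counts scaled to a common library size of 1e6) are TMM-scaled and given as mean ± SD, and standard errors (SE) belong to log2 fold changes. A prior count of 2 was used for log CPM. Coordinates are of GRCh38 and GRCm38 from GENCODE releases 44 and M21, which held 93.2% and 98.9% of the gene IDs. In human data, Y-linked genes and XIST (509 genes) were left out of all steps to protect the donors.

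Before the data were examined, 7 comparisons were set: T3 against T1/T2, FO against T3 and FO against T1/T2 in human, and T2 against T1, T3 against T2, FO against T3 and FO against the mean of T1 and T2 in mouse. Also set were 2 correlations of log2 fold changes between species and an edgeR test of the difference between species over genes that share a symbol. The gene lists were 30: extracellular adenosine and uptake, purine salvage, de novo purine synthesis, MYC targets and ribosome biogenesis, mTORC1-linked nutrient transport and one-carbon genes, glycolysis, sterol synthesis, oxidative phosphorylation, mitochondrially encoded, tricarboxylic acid cycle, fatty acid oxidation, cytosolic ribosomal proteins, cell cycle, quiescence factors, AMPK pathway, autophagy, immature and transitional B cell markers, mature follicular B cell markers, B cell receptor signalling, antigen-induced early response and tolerance genes, handling stress and immediate early genes, interferon-stimulated genes, and markers of memory B cells, plasma cells, marginal zone and B-1 cells, T cells, NK cells, monocytes with macrophages and granulocytes, plasmacytoid dendritic cells, and erythroid cells with platelets. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg over the lists with at least 5 tested members. An adjusted p printed for a list is from camera unless marked otherwise. In mouse the T cell, NK cell and erythroid lists had 3, 1 and 2 tested members and were not tested as lists. Counts of list members that passed are given over all genes, and where stated also adjusted over the list alone.

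The genes named were fixed by rule before the data were examined. They are the 8 largest changes in each direction with an adjusted p under the threshold, at least 5 CPM in the higher group and no overlap of libraries, a panel of 13 genes in every comparison, and up to 4 members of each list with the smallest adjusted p. Immunoglobulin and T cell receptor segments and unnamed or predicted genes were left out of the first set. The same rule applied to the blocked fit was added after the data were seen, as were the genes followed across all mouse stages.

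Alternatives fixed before the data were seen were DESeq2 1.42.0, limma voom, RLE scaling, no count filter, a stricter filter (1 CPM in every library of a group), the replicate block, a log2 fold change minimum of 1, removal of immunoglobulin and mitochondrially encoded genes, a fit of the compared groups alone, removal of each library in turn, and, for lists, an estimated correlation and fry. Chosen after seeing the data were upper quartile scaling, removal of ribosomal RNA genes, a correction for transcript length and GC content (loess span 0.3 per library, with and without the block), removal of each human donor from the blocked fit, a monocyte marker score as covariate, removal of the transitional libraries of mouse 2, and thinning of the 13 mouse libraries to 450364 counts each. The monocyte marker score was the mean log CPM of the monocyte list itself. Library depth was 8815441 to 16641563 counts in human and 546046 to 3986458 in mouse. Ribosomal RNA other than mitochondrial took 7.92 to 19.1% of human counts and 16.3 to 71.0% of mouse counts. With mitochondrial ribosomal RNA, which the thinning kept, left out as well, other counts, in units of 1e6, were 0.422 to 1.985 per mouse transitional library and 0.499 to 0.599 per FO library. The biological coefficient of variation was 0.391 in human and 0.509 in mouse. Libraries were amplified without molecular barcodes, so that intervals and floors from counts cover counting error only. A group with 0 counts was given a floor of 3 counts over the group.

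The steps were tested on simulated counts with the same depths and dispersions. Of 100 genes changed 4-fold, 39 to 50% were recovered in the human comparisons and 23 to 51% in mouse. At 2-fold the shares were 3 to 5% and 0 to 10%. False calls numbered 0 to 6 per comparison with changes present and 0 without. Without changes 1 list was called in human FO against T3 and 0 in each other comparison. A list lowered 1.5-fold was recovered in 7 of 7 comparisons. Counts were simulated independently for each gene, so these list results do not test camera under correlation between genes. A length and GC trend of the mouse size gave 1110 false calls in the uncorrected fit and 0 in the corrected fit. The trend imposed was the one the correction fits, so the 0 does not test a bias of another form. With the correction, 8% of 2-fold and 40% of 4-fold changes were recovered. Smaller changes than 4-fold in single genes are thus mostly below detection, and a gene that did not pass is not shown to be unchanged.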

Results

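Human FO cells carried more transcript of adenosine kinase than T1/T2 cells, and a larger amount, short of the threshold, of the enzyme that makes extracellular adenosine. ADK (ENSG00000156110, hg38 chromosome 10, 74151202 to 74709963), whose product phosphorylates adenosine to AMP, rose from 60 ± 14 to 137 ± 10.9 CPM (2.28-fold, log2 1.19, SE 0.211, adjusted p = 0.0324, n = 3 per group, no overlap of libraries). NT5E (ENSG00000135318, chromosome 6, 85449584 to 85495791), which codes for the ectoenzyme CD73 that makes adenosine from AMP, was at 5.33 ± 6.24 CPM in T1/T2, 17.7 ± 7.75 in T3 and 40.9 ± 15.3 in FO. Its log2 difference between FO and T1/T2 was 2.94 (SE 0.789, adjusted p = 0.0919, and 0.00605 with donor as a block). DCK, another nucleoside kinase, rose from 67.9 ± 2.72 to 120 ± 10.2 CPM (log2 0.83, SE 0.142, adjusted p = 0.0297). PNP, which splits purine nucleosides, fell from 29.7 ± 10.8 to 11 ± 1.83 CPM (log2 -1.44, SE 0.276, adjusted p = 0.0421). The other adenosine genes did not pass. ENTPD1 was at 31.2 ± 9.4 against 19.4 ± 7.84 CPM (adjusted p = 0.299). ADA was at 7.1 ± 3.28 against 6 ± 6.54 (0.933). SLC29A1 was at 2.01 ± 0.886 against 3.29 ± 1.82 (0.66). ALPL was at 0.433 ± 0.23 against 11 ± 8.87 (0.0746, and 0.00706 with donor as a block). ADORA2A was at 28.6 ± 8.55 against 57.5 ± 5.93 (0.142, and 0.0294 with donor as a block). ADORA2A overlaps a readthrough gene, so that its share of the counts is uncertain. Of 19 measured purine salvage genes 2 rose, 1 fell and 16 did not pass, with a median log2 difference of -0.02 and a camera test leaning up (adjusted p = 0.944). The 9 measured genes of extracellular adenosine and uptake gave 0 over all genes, 1 higher and 2 lower adjusted over the list alone, a median of 0.23, a mean of -0.05 and a camera adjusted p of 0.884.

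**Figure D1:**
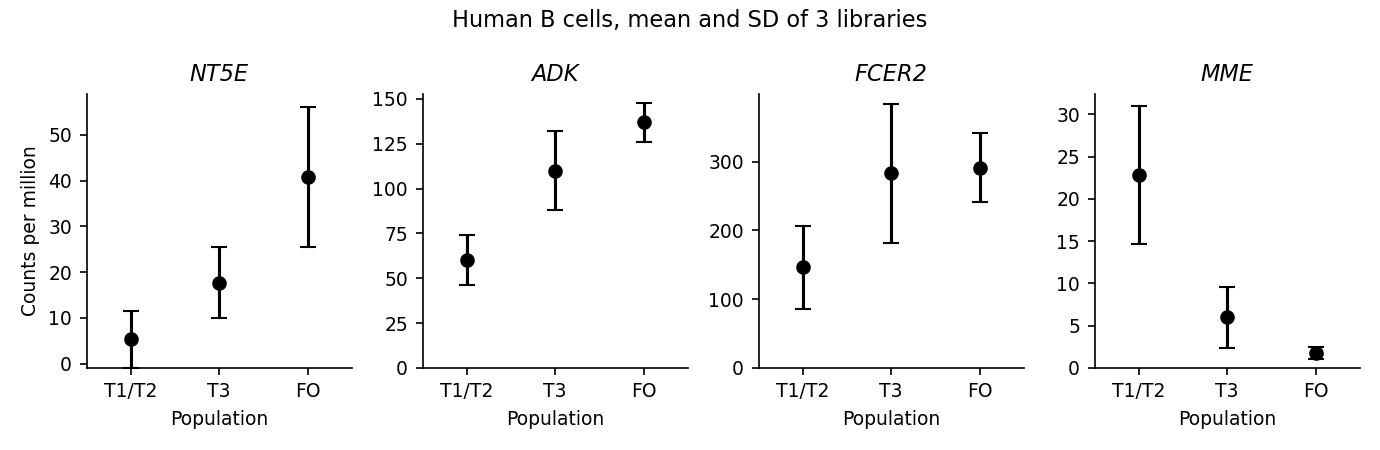
NT5E, ADK, FCER2 and MME transcript in human T1/T2, T3 and FO B cells, in CPM on linear axes. Points are means of 3 libraries per population and bars are SD, for example 137 ± 10.9 for ADK in FO.

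Transcripts of the respiratory chain and of the cytosolic ribosome fell together in human FO cells. Of 77 measured oxidative phosphorylation genes, 10 fell, 0 rose and 67 did not pass over all genes, and 47 fell adjusted over the list alone (median log2 -0.52, camera adjusted p = 7.39e-20, adjusted p = 0.0225 with an estimated correlation). With donor as a block the estimated correlation gave an adjusted p of 0.196, so that this call was lost. COX7B (ENSG00000131174, chromosome X, 77899440 to 77907376), a subunit of complex IV, fell from 96.8 ± 5.13 to 48.9 ± 2.65 CPM (log2 -0.98, SE 0.137, adjusted p = 0.0199). UQCRH of complex III fell from 249 ± 17.5 to 139 ± 7.58 CPM (log2 -0.85, SE 0.128, adjusted p = 0.0211). NDUFB3 of complex I fell from 63.5 ± 4.68 to 34.8 ± 1.11 CPM (log2 -0.87, SE 0.135, adjusted p = 0.0211). The mean score of the list was lower by a log2 difference of -0.637 (pooled SD 0.056), and all 3 FO libraries lay below all 3 T1/T2 libraries. Other library measures moved too. Ribosomal RNA other than mitochondrial took 15.8 ± 3.42% of counts in T1/T2 and 8.46 ± 0.464% in FO, mitochondrial ribosomal RNA 10.1 ± 0.656 and 6.84 ± 0.717%, and genes detected numbered 17770 ± 1037 and 20717 ± 1086. The rho of log CPM with transcript length was below 0 in all T1/T2 libraries and above 0 in all FO libraries. Among 77 ribosomal protein genes 8 fell, 0 rose and 69 did not pass over all genes, and 55 fell adjusted over the list alone (median -0.46, camera adjusted p = 7.39e-20, adjusted p = 0.447 with an estimated correlation). RPS24 fell from 2240 ± 228 to 1060 ± 148 CPM (log2 -1.08, SE 0.17, adjusted p = 0.0211). RPS16 fell from 1790 ± 51.7 to 1090 ± 126 CPM (adjusted p = 0.033). RPS21 fell from 765 ± 57 to 401 ± 73 CPM (adjusted p = 0.0433, and 0.0529 with the length and GC trend removed). The direction of both lists held with RLE and upper quartile scaling (medians -0.54 and -0.45 for the respiratory chain, -0.48 and -0.40 for the ribosome). Of 13 mitochondrially encoded genes 2 rose, MT-ND5 (log2 0.68, adjusted p = 0.029) and MT-CO1 (0.88, adjusted p = 0.0429), with a list median of -0.07, a mean of 0.04 and a camera test leaning up (adjusted p = 0.944).

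Lists of mTORC1-linked and glycolysis transcripts were lower in human FO cells as well. The mTORC1-linked list of amino acid transport and one-carbon genes shifted down (0 higher, 4 lower and 32 not passing of 36, 1 higher and 9 lower adjusted over the list alone, median -0.37, camera adjusted p = 3.07e-05, adjusted p = 0.127 with an estimated correlation). SLC7A5, an amino acid transporter, fell from 43.1 ± 15.9 to 8.58 ± 0.615 CPM (log2 -2.33, SE 0.387, adjusted p = 0.0253). DDIT4, an inhibitor of mTORC1, fell from 145 ± 44.8 to 35.3 ± 3.64 CPM (log2 -2.04, SE 0.338, adjusted p = 0.0253). MTHFD2 fell from 86.1 ± 14 to 36 ± 9.58 (adjusted p = 0.0336). ATF4 fell from 199 ± 8.43 to 114 ± 15.9 (adjusted p = 0.0451). Glycolysis genes shifted down (1 lower of 23, 5 lower adjusted over the list alone, median -0.41, camera adjusted p = 0.0093, adjusted p = 0.127 with an estimated correlation), with LDHA falling from 588 ± 73.3 to 365 ± 32.2 CPM (log2 -0.69, adjusted p = 0.0433). The MYC target list shifted down by a median of -0.11 (1 higher, 1 lower and 59 not passing of 61, camera adjusted p = 0.0224, adjusted p = 0.181 with an estimated correlation). Within it TCOF1 rose from 6.27 ± 1.81 to 23.3 ± 5.41 CPM (adjusted p = 0.0438). AIMP2 fell from 29.3 ± 2.62 to 16.2 ± 1.6 (adjusted p = 0.048), while MYC itself was at 96.9 ± 29 against 115 ± 41.6 CPM (log2 -0.25, SE 0.456, adjusted p = 0.821). The cell cycle list did not pass (camera adjusted p = 0.323), but TOP2A fell from 16.8 ± 3.97 to 4.65 ± 1 CPM (adjusted p = 0.0253). MYBL2 fell from 9.87 ± 1.58 to 2.37 ± 0.657 (adjusted p = 0.0397). MKI67 was listed at 0 in all 9 human libraries, and since it is unknown whether the annotation used counted it, this is not read as absence. Of 36 quiescence factors PIK3IP1 rose from 189 ± 85.8 to 588 ± 47.5 CPM (adjusted p = 0.0407). CDKN2C fell from 1.87 ± 0.197 to 0.129 ± 0.0839 (adjusted p = 0.0303) and 34 did not pass, with a median of -0.07, a mean of -0.01 and a camera test leaning up (adjusted p = 0.944).

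MME, CD9, CCR7, GPR183 and DUSP4 were among the genes that differed between human FO and T1/T2 cells, while the lists of mature follicular markers and B cell receptor signalling did not pass. MME (ENSG00000196549, chromosome 3, 155024124 to 155183704), which codes for the immature-cell antigen CD10, fell from 22.8 ± 8.18 to 1.75 ± 0.692 CPM (log2 -3.70, SE 0.535, adjusted p = 0.02). The list of immature and transitional markers shifted down (3 lower and 20 not passing of 23, 1 higher and 8 lower adjusted over the list alone, median -0.98, camera adjusted p = 2.48e-08, adjusted p = 0.181 with an estimated correlation), with CD9 falling from 140 ± 61.5 to 28.2 ± 6.82 CPM (adjusted p = 0.0211). PPP1R14A fell from 17.5 ± 7.41 to 1.49 ± 0.723 (adjusted p = 0.0178). CD24 was at 35.8 ± 6.44 against 62.4 ± 19.6 CPM (adjusted p = 0.317). CD93 was at 0.59 ± 0.591 against 2.51 ± 1.81 (adjusted p = 0.259). Mature follicular markers split, with 1 higher, 2 lower and 30 not passing of 33, and 7 higher and 3 lower adjusted over the list alone (median 0.15, mean -0.06, camera adjusted p = 0.746). CCR7 (ENSG00000126353, chromosome 17, 40553769 to 40565472), the receptor that leads cells to T cell zones, rose from 783 ± 204 to 2300 ± 729 CPM (log2 1.55, SE 0.276, adjusted p = 0.0324). GPR183 (ENSG00000169508, chromosome 13, 99294539 to 99307399), an oxysterol receptor, fell from 1210 ± 276 to 325 ± 66.9 CPM (log2 -1.90, SE 0.215, adjusted p = 0.0133). CD1C fell from 37.6 ± 15.4 to 1.71 ± 1.2 (log2 -4.41, adjusted p = 0.0336). FCER2 was at 291 ± 50.2 against 146 ± 60.7 CPM (log2 1.00, SE 0.32, adjusted p = 0.142, and 0.00265 with donor as a block). KLF2 was at 3.44 ± 1.33 against 5.25 ± 1.73 (adjusted p = 0.552). The early response and tolerance list shifted down (1 lower of 34, 5 lower adjusted over the list alone, median -0.31, camera adjusted p = 0.00358, adjusted p = 0.127 with an estimated correlation). In it DUSP4, a MAP kinase phosphatase, fell from 57.4 ± 8.16 to 5.38 ± 1.95 CPM (log2 -3.42, SE 0.34, adjusted p = 0.0101).

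By the naming rule, the largest human rises were SYN3 (log2 5.29, adjusted p = 0.0427), CNTNAP2 (4.75, from 1.27 ± 1.07 to 34.1 ± 17.7 CPM, adjusted p = 0.035), LARGE (4.04, 0.0303), AKAP6 (3.91, 0.0427), IL13RA1 (3.76, from 0.938 ± 0.702 to 13.1 ± 4.59 CPM, 0.0211), LSR (3.70, from 1.23 ± 0.538 to 16.2 ± 2.81 CPM, 0.02), SCML1 (2.69, 0.0302) and INADL (2.66, 0.02). The largest falls were in the transcription factor gene SOX5 (183 counts in T1/T2 against 2 in FO, ratio 110, counting interval 32.5 to 969, adjusted p = 0.0178), GNG3 (log2 -5.43, 0.02), CALHM2 (-5.37, 0.0471), C10orf128 (-5.29, 0.0474), CLECL1 (-4.77, 0.0211), CD1C (-4.41, 0.0336), FOSL2 (-3.79, from 71 ± 58.4 to 5.1 ± 1.15 CPM, 0.0324) and MME (-3.70, 0.02). Among those named by the same rule from the fit with donor as a block were CAV1 (log2 4.07, adjusted p = 0.00836), RHPN2 (3.42, 0.0315), ZBTB32 (-5.68, 0.0072) and BMP3 (-5.38, 0.00414).

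Markers of other cells moved beside these genes in human. The monocyte, macrophage and granulocyte list was lower in FO (1 lower of 17, 3 lower adjusted over the list alone, median -2.27, camera adjusted p = 5.9e-07, adjusted p = 0.323 with an estimated correlation), with ITGAM at 1.32 ± 0.757 against 14.1 ± 2.9 CPM (adjusted p = 0.0475). S100A9 was at 8.96 ± 7.87 against 72.8 ± 59.9 (0.123, and 0.00136 with donor as a block). S100A8 was at 5.5 ± 4.64 against 37.3 ± 31.4 (0.167, and 0.00152 with donor as a block). Marginal zone and B-1 markers shifted down (2 lower of 16, 1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00429, adjusted p = 0.319 with an estimated correlation). Memory B cell markers did not pass (0 of 14 over all genes, 2 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.242), among them TNFRSF13B at 2.5 ± 2.05 against 39.6 ± 35 CPM (adjusted p = 0.0536, and 0.000842 with donor as a block). Camera adjusted p-values of the other lists were 0.0978 for NK cell markers, 0.119 for plasmacytoid dendritic cell markers, 0.262 for erythroid and platelet markers, 0.336 for plasma cell markers, 0.0978 for interferon-stimulated genes, 0.848 for autophagy, and 0.364 each for T cell markers, handling stress genes, de novo purine synthesis, sterol synthesis and the tricarboxylic acid cycle. They were 0.944 for fatty acid oxidation and for B cell receptor signalling and 0.961 for the AMPK pathway. JUN of the handling stress list rose from 104 ± 30.1 to 273 ± 27.2 CPM (adjusted p = 0.031, and 0.0513 with the length and GC trend removed).

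In all, the edgeR test called 206 of 12779 genes between human FO and T1/T2 (74 higher, 132 lower). With donor as a block it called 1248 (435 higher, 813 lower), among them all 206, and 42, 381 and 982 with donor 1, 2 or 3 out. DESeq2 called 1104, and a fit of the compared groups alone 69. The count rests on every FO library, since it was 0 without FO replicate 1, 2 without replicate 2 and 0 without replicate 3. It ranged from 81 to 264 without a T1/T2 library, and it was 10 with a monocyte marker score as covariate. Monocyte markers were themselves lower in FO, so that covariate also takes up part of the group difference. Of the called genes 35.9% were higher with TMM scaling and 50% with upper quartile scaling.

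Mean levels of ADK, NT5E, FCER2 and MME in human T3 cells lay between those of T1/T2 and FO. ADK was at 110 ± 22 CPM in T3 against 60 ± 14 in T1/T2 (log2 0.88, SE 0.209, adjusted p = 0.305, and 0.0306 with donor as a block). NT5E was at 17.7 ± 7.75 against 5.33 ± 6.24 (log2 1.73, SE 0.765, adjusted p = 0.523). MME was at 5.96 ± 3.65 against 22.8 ± 8.18 CPM (0.318, and 0.0355 with donor as a block). FCER2 was at 283 ± 101 against 146 ± 60.7 (0.408, and 0.0307). CCR7 was at 1730 ± 375 against 783 ± 204 (0.305, and 0.0126). The kinase gene PIM1 was at 50.7 ± 17.9 against 20.7 ± 5.97 (0.305, and 0.0306). ENTPD1 was at 34.7 ± 2.35 against 19.4 ± 7.84 CPM (0.462). ADORA2A was at 29.3 ± 12.8 against 57.5 ± 5.93 (0.408). ADA was at 8.21 ± 5.78 against 6 ± 6.54 (0.916). SLC29A1 was at 2.08 ± 1.58 against 3.29 ± 1.82 (0.827). MYC was at 93.5 ± 51.9 against 115 ± 41.6 (0.87). KLF2 was at 4.53 ± 2.38 against 5.25 ± 1.73 (0.917). CD24 was at 57.3 ± 34.9 against 62.4 ± 19.6 (0.944). CD93 was at 1.42 ± 0.86 against 2.51 ± 1.81 (0.798). Other genes that passed only with donor as a block were IL23A (log2 2.08, adjusted p = 0.0355), INADL (1.95, 0.0339), P2RY14 (1.63, 0.0403), APOL3 (1.63, 0.0306), STAG3L3 (1.52, 0.0355) and HMHA1 (1.05, 0.0291) on the higher side. On the lower side were BMP3 (-3.86, 0.0499), ADM (-2.20, 0.0403), GPER1 (-2.13, 0.00954), DMD (-1.66, 0.0306) and the chemokine gene CCL4 (-1.57, 0.0306). CCL4L2 (-2.15, 0.00954) and CCL3L3 (-2.04, 0.0334) also passed, but these are near-identical copies of CCL4 and CCL3 and the assignment of their reads is uncertain.

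Without the block the edgeR test called 0 of 12779 genes between T3 and T1/T2, against 1211 at an unadjusted p under 0.05 (smallest adjusted p 0.26). DESeq2 called 191, limma voom 0 and the blocked edgeR fit 47 (20 higher, 27 lower). With donor 1, 2 or 3 out the blocked fit called 0, 1 and 9. In this comparison 7 lists passed camera, and every one had 0 genes passing over all genes. The respiratory chain (median -0.29, adjusted p = 5.67e-11, adjusted p = 0.106 with an estimated correlation) and ribosomal proteins (median -0.25, 5.67e-11, adjusted p = 0.86 with an estimated correlation) shifted down, with COX7B at 68.4 ± 5.88 against 96.8 ± 5.13 CPM, UQCRFS1 at 112 ± 9.95 against 156 ± 6.77, and RPS24 at 1440 ± 283 against 2240 ± 228 (0.325, and 0.0306 with donor as a block). Lower lists were also immature markers (median -0.55, 0.000532, adjusted p = 0.573 with an estimated correlation), early response genes (-0.38, 0.00267, adjusted p = 0.184 with an estimated correlation), mTORC1-linked genes (-0.27, 0.00605, adjusted p = 0.23 with an estimated correlation) and MYC targets (-0.15, 0.00826, adjusted p = 0.213 with an estimated correlation). CD9 was at 51.9 ± 18.2 against 140 ± 61.5 CPM and SLC7A5 at 17.8 ± 9.06 against 43.1 ± 15.9. T cell markers were higher (median 0.80, 0.0214, adjusted p = 0.23 with an estimated correlation), with ZAP70 at 1.23 ± 0.842 against 0.318 ± 0.118 CPM. Camera gave 0.995 for extracellular adenosine (median 0.45, mean -0.03) and 0.63 for purine salvage (median -0.05, mean 0.28, leaning up).

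Between T3 and FO no human gene passed without the donor block. GPR183 was at 325 ± 66.9 against 644 ± 76.6 CPM (log2 -0.99, SE 0.21, adjusted p = 0.95). It passed with donor as a block (0.0359), but not with the length and GC trend removed as well (0.0769), nor with the block and donor 1 or donor 2 out (0.682 and 0.238). NT5E was at 40.9 ± 15.3 in FO against 17.7 ± 7.75 CPM in T3 (log2 1.21, SE 0.73, adjusted p = 1). ADK was at 137 ± 10.9 against 110 ± 22 (0.31, SE 0.207). MME was at 1.75 ± 0.692 against 5.96 ± 3.65 (-1.75, SE 0.512). DUSP4 was at 5.38 ± 1.95 against 25.9 ± 7.7 (-2.27, SE 0.328, adjusted p = 0.547). The edgeR test called 0 genes here, against 355 at an unadjusted p under 0.05, and DESeq2 called 17, limma voom 0 and the blocked edgeR fit 2. The blocked fit called 0 with the length and GC trend removed, and 0, 0 and 23 with donor 1, 2 or 3 out.

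A set of 12 lists was lower in human FO than in T3, each with 0 genes passing over all genes, and every call was lost with an estimated correlation. With the monocyte marker score as covariate 5 of the 12 stayed called, among 9 lists (2 higher, 7 lower). Since the score is built from a list that is lower in FO, it also takes up part of the group difference. Monocyte markers had the largest shift (median -1.86, camera adjusted p = 8.59e-16, adjusted p = 0.129 with an estimated correlation), with S100A9 at 8.96 ± 7.87 against 55.3 ± 36.1 CPM and TYROBP at 3.24 ± 2.62 against 13.6 ± 10. The respiratory chain (-0.25, 3.77e-13, adjusted p = 0.071 with an estimated correlation), ribosomal proteins (-0.20, 3.77e-13, adjusted p = 0.441 with an estimated correlation), NK markers (-1.72, 1.27e-08, adjusted p = 0.129 with an estimated correlation) and immature markers (-0.60, 1.76e-08, adjusted p = 0.137 with an estimated correlation) followed. Memory markers (-0.91, 3.4e-06, adjusted p = 0.151 with an estimated correlation), erythroid markers (-0.77, 0.000175, adjusted p = 0.129 with an estimated correlation), mTORC1-linked genes (-0.21, 0.000228, adjusted p = 0.129 with an estimated correlation) and glycolysis (-0.29, 0.00029, adjusted p = 0.0806 with an estimated correlation, LDHA at 365 ± 32.2 against 532 ± 21.7 CPM) were lower too. The last were marginal zone markers (-0.46, 0.000581, adjusted p = 0.151 with an estimated correlation), plasmacytoid dendritic cell markers (-0.28, 0.0137, adjusted p = 0.129 with an estimated correlation) and sterol synthesis (-0.16, 0.0348, adjusted p = 0.129 with an estimated correlation). With donor as a block 3 more lists were called, mitochondrially encoded genes (0.0842, and 0.0434 with the block, higher), interferon-stimulated genes (0.0967, and 0.0499, lower) and plasma cell markers (0.0675, and 0.0434, lower). These were lost as well with the block and an estimated correlation (0.571, 0.571 and 0.201).

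Fcer2a, Cr2, Ighd and Icosl were among the genes that rose from mouse T1 to T2. Fcer2a (ENSMUSG00000005540, mm10 chromosome 8, 3681737 to 3694175), which codes for the low-affinity IgE receptor CD23 that marks T2 cells, rose 12.8-fold from 49.9 ± 6.08 to 640 ± 135 CPM (log2 3.68, SE 0.23, adjusted p = 1.06e-07, n = 3 per group). Complement receptor gene Cr2 rose from 37.2 ± 11.4 to 142 ± 18.3 CPM (log2 1.92, adjusted p = 0.00214). Ighd rose from 229 ± 10.3 to 625 ± 180 (1.45, adjusted p = 0.00835). Icosl rose from 8.21 ± 3.64 to 52.9 ± 29.4 (2.61, adjusted p = 0.0124, and 0.0645 with mouse as a block). Mature follicular markers shifted up as a list (5 higher and 25 not passing of 30, 12 higher and 2 lower adjusted over the list alone, median 0.61, camera adjusted p = 1.51e-10, adjusted p = 0.00545 with an estimated correlation). MYC targets shifted up too (2 higher and 58 not passing of 60, 9 higher adjusted over the list alone, median 0.67, camera adjusted p = 1.98e-10, adjusted p = 0.00545 with an estimated correlation). Srm rose from 8.07 ± 1.9 to 64.1 ± 30.9 CPM (adjusted p = 0.00835). Ncl rose from 106 ± 1.98 to 238 ± 13.2 (adjusted p = 0.0119), with Nolc1 at 55.6 ± 6.77 against 18.4 ± 4.37 (0.0963). Myc was at 57.4 ± 8.33 against 14 ± 12 (log2 2.12, SE 0.494, adjusted p = 0.0916). Impdh2 of the guanine nucleotide path rose from 42.9 ± 5.61 to 116 ± 21.5 CPM (adjusted p = 0.0131), while its de novo purine list reached a camera adjusted p of 0.0537 (0.0398 with mouse as a block, and 0.175 with the block and an estimated correlation).

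Jchain, Vpreb3 and Ms4a1 were among the genes that fell from mouse T1 to T2, while the immature marker list did not pass (1 lower and 17 not passing of 18, camera adjusted p = 0.088). Jchain fell from 663 ± 379 to 119 ± 69.2 CPM (log2 -2.48, SE 0.417, adjusted p = 0.0167). Vpreb3, a surrogate light chain partner, fell from 407 ± 87.7 to 141 ± 27.7 (-1.53, adjusted p = 0.0212). Ms4a1 fell from 3690 ± 398 to 1790 ± 196 (-1.04, adjusted p = 0.0167). Ifi27l2a fell from 582 ± 41.6 to 194 ± 13.6 (-1.58, adjusted p = 0.00214). Crip1 fell from 294 ± 18.1 to 98.4 ± 21.5 (-1.58, adjusted p = 0.00835). Chchd10 fell from 242 ± 19.6 to 80 ± 20.9 (-1.59, adjusted p = 0.00835). Fcrla fell from 470 ± 27.1 to 238 ± 24.9 (-0.98, adjusted p = 0.0243, and 0.0881 with the length and GC trend removed). Cst3 fell from 202 ± 22.8 to 80.6 ± 24.4 (-1.32, adjusted p = 0.0472, and 0.0778 with mouse as a block). Egr2 rose from 0.8286 ± 0.515 to 15.2 ± 3.33 CPM (log2 4.23, adjusted p = 0.00767). Piezo1 rose from 3.19 ± 1.3 to 17.3 ± 3 (2.37, adjusted p = 0.0231, 0.0965 with mouse as a block, and 0.0575 with the length and GC trend removed). Abcc4 rose from 3 to 98 counts (ratio 47.7, counting interval 12 to 170, adjusted p = 0.00835). Setbp1 rose from 0 to 40 counts (at least 14.8-fold higher, adjusted p = 0.0124, and 0.0652 with mouse as a block). Ly6d was at 1100 ± 328 against 2410 ± 504 CPM (adjusted p = 0.0529, and 0.0226 with mouse as a block). Cd24a was at 992 ± 106 against 1670 ± 239 (adjusted p = 0.142).

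Other lists called between mouse T2 and T1 were lost with an estimated correlation. Early response genes shifted up (1 higher of 27, 8 higher adjusted over the list alone, median 0.62, or 0.36 with genes at 0 counts held at their bound, camera adjusted p = 0.0019, adjusted p = 0.155 with an estimated correlation), as did cell cycle genes (0 of 25, 0.0358, adjusted p = 0.112 with an estimated correlation) and glycolysis (0 of 18, 0.0362, adjusted p = 0.146 with an estimated correlation, and 0.0517 with the length and GC trend removed). Lower were the respiratory chain (0 of 76, median -0.29, 0.000154, adjusted p = 0.146 with an estimated correlation), ribosomal proteins (0 of 77, median -0.20, 0.0019, adjusted p = 0.633 with an estimated correlation), plasma cell markers (1 of 8, 4 lower adjusted over the list alone, 0.00768, adjusted p = 0.0753 with an estimated correlation, Mzb1 at 90.6 ± 32.6 against 176 ± 21.7 CPM), autophagy (0 of 31, 0.0144, adjusted p = 0.146 with an estimated correlation) and interferon-stimulated genes (0 of 27, 0.0155, adjusted p = 0.0753 with an estimated correlation). With the length and GC trend removed both the respiratory chain (median -0.14, 0.0516) and the ribosomal proteins (median -0.05, 0.313) lost their call. Extracellular adenosine gave 0.061 (0 of 9, median -0.45, and 0.046 with that trend removed) and purine salvage 0.464 (0 of 15, median 0.05, mean -0.05, leaning down). With mouse as a block fatty acid oxidation (0.061, and 0.0398, lower) and handling stress genes (0.061, and 0.0398, higher) were called, and with the block and an estimated correlation these were lost (0.175 and 0.38). Other genes of the fixed panel did not pass. Adora2a was at 6.16 ± 1.13 against 13.3 ± 4.79 CPM (adjusted p = 0.724). Slc29a1 was at 3.12 ± 0.811 against 12.7 ± 6.73 (0.387). Entpd1 was at 7.45 ± 6.5 against 17.9 ± 3.69 (0.706). Adk was at 5.19 ± 3.06 against 2.3 ± 2.15 (0.811). Ada was at 2.59 ± 2.38 against 2.42 ± 2.31 (0.995). Klf2 was at 74.2 ± 50.6 against 101 ± 56.3 CPM (0.788). Cd93 was at 16.5 ± 15.9 against 24.6 ± 3.65 (0.783). Nt5e, Mki67 and Mme had too few counts to be tested in mouse, with 0, 1, 6 and 8 Nt5e counts over the libraries of T1, T2, T3 and FO.

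The edgeR test called 26 of 9392 genes between mouse T2 and T1 (14 higher, 12 lower), against 1026 at an unadjusted p under 0.05. With mouse as a block it called 21, of which 20 were shared. DESeq2 called 212, limma voom 62 and a fit of the compared groups alone 2. The count ranged from 5 without T1 replicate 1 to 44 without T2 replicate 1.

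**Figure D2:**
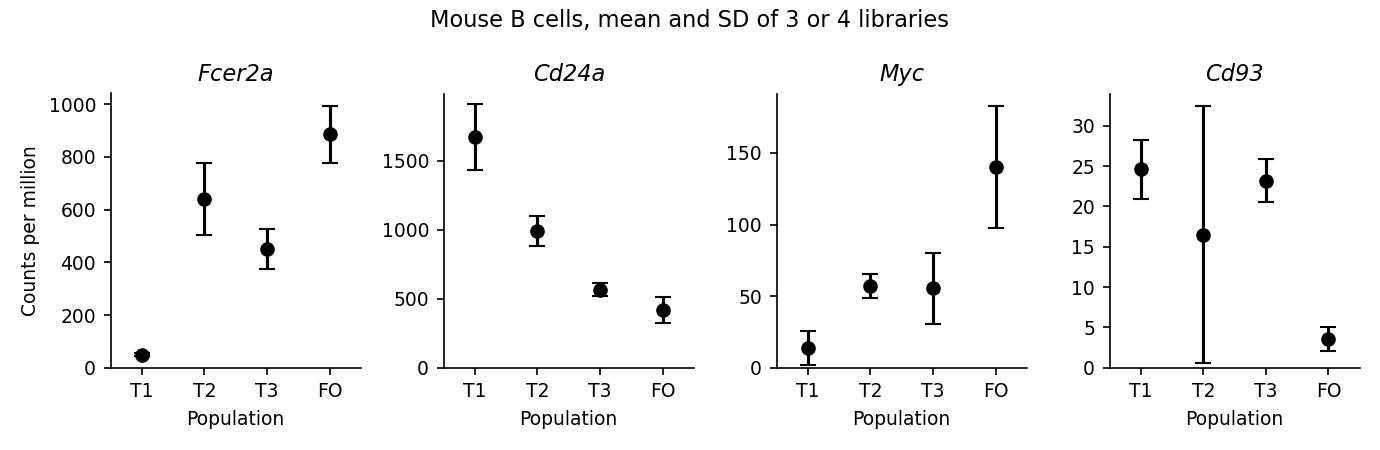
Fcer2a, Cd24a, Myc and Cd93 transcript in mouse T1, T2, T3 and FO B cells, in CPM on linear axes. Points are means of 3 libraries (4 for FO) and bars are SD, for example 640 ± 135 for Fcer2a in T2.

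The edgeR test called few genes between mouse T3 and T2, and most of them fell. Ifi30, a lysosomal thiol reductase gene, fell from 576 ± 60.2 to 195 ± 35.5 CPM (log2 -1.57, SE 0.2, adjusted p = 0.00439). The complement gene Cfp fell from 186 ± 20 to 54.2 ± 14.7 (-1.79, adjusted p = 0.0104). Jchain fell from 119 ± 69.2 to 10 ± 1.05 (-3.55, adjusted p = 0.0104). Pld4 fell from 238 ± 25.1 to 82 ± 20 (-1.54, adjusted p = 0.0191, and 0.0672 with the length and GC trend removed). Nedd4, a ubiquitin ligase gene, fell from 95.4 ± 29.9 to 21.6 ± 3.43 CPM (-2.13, adjusted p = 0.0153, and 0.0776 with mouse as a block). Rassf4 fell from 44.1 ± 5.05 to 7.37 ± 4.95 (-2.60, adjusted p = 0.0454, 0.134 with the block, and 0.0725 with the trend removed). Clec2i rose from 16.8 ± 9.07 to 79.7 ± 27.3 (2.24, adjusted p = 0.0454, 0.125 with the block, and 0.0672 with the trend removed). Dennd5b rose from 14.2 ± 3.14 to 45.4 ± 12.9 (1.69, adjusted p = 0.0454, and 0.141 with the block). These were all 8 genes called (2 higher, 6 lower), against 1031 at an unadjusted p under 0.05, and 4 were called with mouse as a block. DESeq2 called 159 and a fit of the compared groups alone 0, and the count ranged from 5 to 15 with 1 library left out. Panel genes did not pass. Fcer2a was at 451 ± 74.3 against 640 ± 135 CPM (adjusted p = 0.377). Cd24a was at 567 ± 44.9 against 992 ± 106 (0.159). Myc was at 55.4 ± 24.7 against 57.4 ± 8.33 (0.993). Klf2 was at 77.7 ± 25 against 74.2 ± 50.6 (0.987). Cd93 was at 23.2 ± 2.71 against 16.5 ± 15.9 (0.83). Slc29a1 was at 12.7 ± 8.64 against 3.12 ± 0.811 (0.403). Entpd1 was at 4.7 ± 5.48 against 7.45 ± 6.5 (0.897). Ada was at 4.31 ± 6.99 against 2.59 ± 2.38 (0.939). Adk was at 3.14 ± 4.18 against 5.19 ± 3.06 (0.905), and Adora2a had 0 counts against 53 (at least 9.66-fold lower, 0.13). Mitochondrially encoded genes were higher as a list (0 over all genes and 7 of 12 adjusted over the list alone, median 0.74, camera adjusted p = 2.81e-05, adjusted p = 0.787 with an estimated correlation), with mt-Nd4 at 1610 ± 327 against 822 ± 77 CPM. Ribosomal proteins were higher as well (0 of 77, median 0.18, 0.00382, adjusted p = 0.808 with an estimated correlation). Lists of extracellular adenosine (0.504), purine salvage (0.553), MYC targets (0.538), the respiratory chain (0.539) and mature follicular markers (0.539) did not pass.

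Mouse FO cells had more transcript of follicular markers and less of immature markers than T1 and T2 cells. Fcer2a was at 885 ± 108 CPM (n = 4) against 49.9 ± 6.08 in T1 and 640 ± 135 in T2 (log2 2.31 against their mean, SE 0.163, adjusted p = 4.16e-08). Ighd rose to 3240 ± 602 (3.10, SE 0.181, adjusted p = 4.23e-09). Gpr183 rose from 19.8 ± 8.07 and 31.6 ± 5.68 to 172 ± 25.3 (2.78, SE 0.251, adjusted p = 5.15e-07). The mature follicular list rose (18 higher, 5 lower and 7 not passing of 30, 18 and 5 adjusted over the list alone, median 1.12, camera adjusted p = 3.18e-06, adjusted p = 0.0179 with an estimated correlation, and 0.0569 with mouse as a block too). Cd24a (ENSMUSG00000047139, chromosome 10, 43578284 to 43584265) fell from 1670 ± 239 and 992 ± 106 to 419 ± 94 CPM (-1.62, SE 0.171, adjusted p = 2.53e-06). Cd93 fell from 24.6 ± 3.65 and 16.5 ± 15.9 to 3.55 ± 1.48 (-2.48, SE 0.571, adjusted p = 0.00251). Vpreb3 fell to 16.7 ± 7.15 (-3.84, adjusted p = 5.24e-08). Spib fell to 175 ± 41 (-2.28, adjusted p = 1.62e-07). Ly6d fell to 117 ± 21.3 (-3.79, adjusted p = 4.23e-09). Immature markers fell as a list (1 higher, 11 lower and 6 not passing of 18, the same counts adjusted over the list alone, median -1.48, camera adjusted p = 8.12e-06, adjusted p = 0.0179 with an estimated correlation).

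Respiratory chain and ribosomal protein transcripts fell in mouse FO cells too. Of 76 respiratory chain genes 67 fell, 1 rose and 8 did not pass (69 lower adjusted over the list alone, median -1.66, camera adjusted p = 2.38e-24, adjusted p = 0.0179 with an estimated correlation). Uqcrh (ENSMUSG00000063882, chromosome 4, 116066965 to 116075071) fell from 206 ± 38.6 and 116 ± 8.72 to 29.5 ± 3.3 CPM (log2 -2.39, SE 0.21, adjusted p = 4.14e-07). Cox4i1 (ENSMUSG00000031818, chromosome 8, 120668222 to 120674207) fell from 431 ± 57.8 and 319 ± 81 to 97.2 ± 14.2 (-1.93, SE 0.186, adjusted p = 9.89e-07). Of 77 ribosomal protein genes 73 fell and 4 did not pass (median -1.11, camera adjusted p = 5.17e-21, adjusted p = 0.252 with an estimated correlation). Rpl41 was at 178 ± 44.4 against 768 ± 138 and 496 ± 43.2 CPM (-1.80, adjusted p = 2.53e-06). Tricarboxylic acid cycle genes fell (1 higher, 11 lower of 24, median -0.63, camera adjusted p = 0.00684, adjusted p = 0.201 with an estimated correlation). Sdhb fell to 24.6 ± 3.67 (adjusted p = 8.75e-05). Mdh1 fell to 37.5 ± 13.4 CPM (adjusted p = 0.000348). Both directions held with RLE scaling (median -1.44 for the respiratory chain and -0.89 for the ribosome) and upper quartile scaling (-1.61 and -1.06). With the length and GC trend of each library removed the respiratory median was -0.88 (camera adjusted p = 2.14e-10) and the ribosomal median -0.27 (0.000598). Of 12 mitochondrially encoded genes 3 rose and 1 fell (median 0.07, camera adjusted p = 0.583). Of these mt-Nd5 rose to 3060 ± 534 (1.51, adjusted p = 2.84e-05). Likewise mt-Co1 rose to 6120 ± 1210 (1.31, adjusted p = 3.04e-05). In contrast mt-Nd4 fell to 356 ± 40.8 CPM (-1.10, adjusted p = 0.000344). With that trend removed the list was higher (median 1.55, 1.7e-09) and mt-Nd4 was at 0.14 (adjusted p = 0.633).

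**Figure D3:**
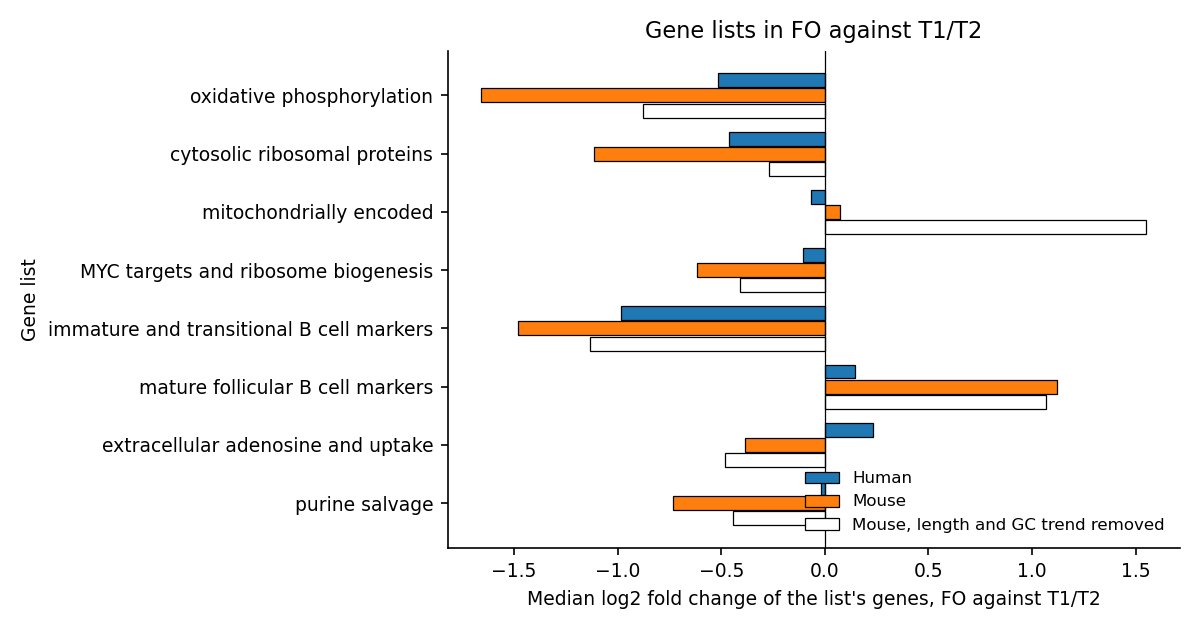
Median log2 fold change of 8 gene lists in FO against T1/T2 for human (3 against 3 libraries) and mouse (4 against 6), and for mouse with each library's length and GC trend removed; bars start at 0. The respiratory chain was at -0.52 in human, -1.66 in mouse and -0.88 in mouse with the trend removed.

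Activation and quiescence genes rose together in mouse FO cells. Egr1 rose from 45.1 ± 22.4 and 94.1 ± 51.6 to 1720 ± 635 CPM (log2 4.72, SE 0.405, adjusted p = 3.05e-07). Nr4a1 rose from 7.67 ± 4.58 and 31 ± 17.2 to 633 ± 298 (5.29, adjusted p = 4.06e-06). Irf4 rose from 44 ± 8.72 and 52.5 ± 7.34 to 238 ± 64.9 (2.304, adjusted p = 1.61e-06). Their early response list rose (12 higher, 5 lower of 27, median 0.98, camera adjusted p = 0.00512, adjusted p = 0.252 with an estimated correlation). Handling stress and immediate early genes rose too, with handling untested (9 higher, 3 lower of 19, median 0.84). The camera adjusted p was 0.00275, and 0.249 with an estimated correlation. Fosb rose from 6.9 ± 1.88 and 10.2 ± 2.77 to 378 ± 70.3 (5.46, adjusted p = 4.47e-09). Jun rose to 559 ± 88.5 (1.94, adjusted p = 4.24e-07). Dusp1 rose to 441 ± 89 CPM (2.31, adjusted p = 1.91e-06). Quiescence factors rose (12 higher, 4 lower of 33, median 0.68, camera adjusted p = 0.00684, adjusted p = 0.0733 with an estimated correlation, and a median of 0.19 with the length and GC trend removed), with Zfp36l1 at 999 ± 180 (2.52, adjusted p = 2.41e-06). Tsc1 was at 70.9 ± 8.7 (4.02, adjusted p = 1.3e-05) and Slfn2 fell to 37.3 ± 7.15 CPM (-1.95, adjusted p = 1.23e-05). Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374) rose from 14 ± 12 and 57.4 ± 8.33 to 140 ± 42.5 CPM (2.35, SE 0.365, adjusted p = 9.85e-05), while MYC targets had 4 higher and 19 lower of 60 (median -0.62, camera adjusted p = 0.0849).

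Purine and adenosine genes split in mouse FO. Of 9 measured adenosine genes Enpp1 rose from 10 ± 7.58 and 11.1 ± 5.22 to 33.3 ± 13.9 CPM (log2 1.68, adjusted p = 0.0216, and 0.71, 0.38 with the length and GC trend removed). Slc28a2, a nucleoside transporter gene, fell from 101 ± 31.2 and 73.9 ± 14.1 to 43.6 ± 10.4 (-0.99, adjusted p = 0.00523) and 7 did not pass (median -0.38, camera adjusted p = 0.764). Of 15 salvage genes 1 rose, Ampd2 (2.10, adjusted p = 0.00261), and 5 fell, among them Hprt from 50.8 ± 5.91 and 45.8 ± 12.3 to 18.1 ± 6.28 CPM (-1.41, adjusted p = 0.00301). With that trend removed Hprt was at -0.07 (adjusted p = 0.902), and at 0.0271 with mouse as a block too (0.972), so that its call was lost. The salvage list had a median of -0.73 and a camera adjusted p of 0.326. De novo purine genes had 4 lower of 13 (0.165). Adk was at 2.27 ± 0.404 against 2.3 ± 2.15 and 5.19 ± 3.06 CPM (log2 -0.64, SE 1.01, adjusted p = 0.652). Entpd1 was at 15.6 ± 8.31 (0.41, 0.702). Ada was at 3.27 ± 1.65 (0.33, 0.854). Slc29a1 was at 4.78 ± 2.81 (-0.38, 0.698). Adora2a was at 5.01 ± 4.21 (-0.85, 0.39). Klf2 was at 59.7 ± 6.28 (-0.54, 0.257).

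The largest mouse changes by the naming rule ran mostly from or to few counts. Jchain had 0 counts in FO against 5524 in T1 and T2 (at least 630-fold lower, adjusted p = 1.33e-07), Cplx2 0 against 211 (at least 21.2-fold lower, 0.000618) and Zeb2os 0 against 56 (at least 5.96-fold lower, 0.0152, and 0.0628 with mouse as a block). Ratios from 1 or 2 counts were 126 for Wfdc21 (counting interval 21.5 to 4740), 81.5 for Mgst1 (14.9 to 3290), 59.1 for Adssl1 (16.1 to 480) and 55.6 for Dynlt1-ps1 (10.2 to 2240). Cfp fell from 228 ± 30.9 and 186 ± 20 to 5 ± 1.9 CPM (-5.35, SE 0.285, adjusted p = 2.09e-09). Higher in FO were Lincpint (133 counts against 0, at least 151-fold), Slc4a11 (at least 93-fold), Ryr2 (at least 75.6-fold), Map3k19 (at least 59.5-fold), Nid1 (at least 47.7-fold) and Hspg2 (at least 40.3-fold), Nr4a3 (ratio 313, counting interval 40.3 to 8870) and L1cam (220, 41.6 to 9150).

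Markers of other mouse cells and the remaining lists were as follows. Monocyte markers were lower in FO (4 of 6, median -2.39, camera adjusted p = 0.0168, adjusted p = 0.151 with an estimated correlation, and 0.167 with the length trend removed), with Cst3 falling to 28.5 ± 4.22 (-2.16, adjusted p = 3.74e-06). Ctss fell to 102 ± 17.6 CPM (-1.41, adjusted p = 1.57e-05, and -0.26, 0.255 with the length trend removed). Plasma cell markers had 1 higher and 4 lower of 8 (0.154), with Mzb1 at 29.1 ± 3.39 against 176 ± 21.7 and 90.6 ± 32.6 CPM. B cell receptor signalling had 13 higher and 9 lower of 43 (0.175), Nfatc1 rising to 315 ± 31.6 (2.48, adjusted p = 6.16e-08) and Cd79b falling to 667 ± 152 CPM (-2.24, adjusted p = 1.99e-07). Glycolysis had 7 lower of 18 (0.161, and 0.0169 with the length trend removed), with Ldha falling to 68.8 ± 12.6 CPM (-1.80, adjusted p = 1.96e-05). Camera adjusted p-values were 0.764 for mTORC1-linked genes, 0.786 for sterol synthesis, 0.165 for fatty acid oxidation, 0.56 for the cell cycle, 0.193 for the AMPK pathway, 0.969 for autophagy, 0.275 for interferon-stimulated genes, 0.214 for memory markers, 0.764 for marginal zone markers and 0.12 for plasmacytoid dendritic cell markers.

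The edgeR test called 3578 of 9392 genes between mouse FO and the mean of T1 and T2 (1712 higher, 1866 lower), 2914 with mouse as a block (2858 shared) and 2475 with the length and GC trend removed (1088 higher, 1387 lower, 2036 shared). The log2 fold changes had a Spearman rho of 0.51 with transcript length. All 4 FO libraries had 64.7 to 71.0% ribosomal RNA, against 16.3 to 64.2% in the 9 transitional libraries, and their log CPM had a rho with length of 0.459 to 0.475, against -0.398 to -0.00117. RLE scaling raised the median of all genes by 0.219 on the log2 scale, and the higher share of called genes went from 47.8 to 58%. Population and any FO library batch cannot be separated, and preparation dates are not given.

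**Figure D4:**
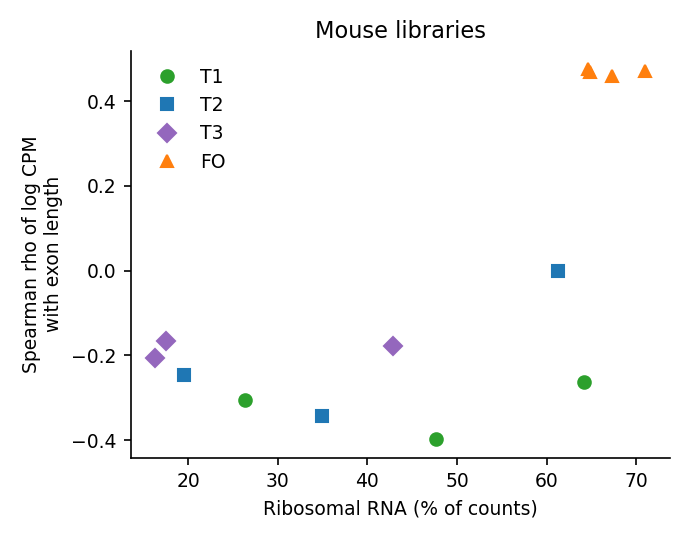
Ribosomal RNA (% of counts) and Spearman rho of gene-centred log CPM with exon length in 13 mouse libraries, by population. The 4 FO libraries lie at 64.7 to 71.0% and 0.459 to 0.475.

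Against T3, respiratory chain and ribosomal protein transcripts were lower in mouse FO cells, while the early response list (8 higher, 5 lower of 27, median 0.50, camera adjusted p = 0.158) and the handling stress list (8 higher, 3 lower of 19, median 0.29, 0.158) did not pass. Respiratory chain genes fell (1 higher, 65 lower and 10 not passing of 76, 68 lower adjusted over the list alone, median -1.60, camera adjusted p = 1.87e-26, adjusted p = 0.00866 with an estimated correlation). Cox4i1 fell from 375 ± 32.1 to 97.2 ± 14.2 CPM (log2 -1.95, SE 0.206, adjusted p = 1.1e-05). Uqcrh fell from 138 ± 32.5 to 29.5 ± 3.3 (-2.23, adjusted p = 9.77e-06). Ribosomal protein genes fell (70 lower of 77, 72 adjusted over the list alone, median -1.19, 2.53e-28, adjusted p = 0.239 with an estimated correlation). With the length and GC trend removed the medians were -0.999 for the respiratory chain (3.37e-11) and -0.54 for ribosomal proteins (2.03e-08). Rpl34 fell from 513 ± 46.3 to 134 ± 33.1 CPM (-1.94, adjusted p = 1e-05). Mature follicular markers rose (15 higher, 5 lower of 30, median 0.91, 0.000816, adjusted p = 0.0914 with an estimated correlation). Bank1 rose from 210 ± 38.8 to 933 ± 55.8 (2.15, adjusted p = 1.28e-05). Gpr183 rose from 28.7 ± 7.17 to 172 ± 25.3 (2.56, adjusted p = 4.98e-05). Fcer2a rose from 451 ± 74.3 to 885 ± 108 CPM (0.97, SE 0.197, adjusted p = 0.00161). Ltb fell from 422 ± 38 to 76.3 ± 12.4 (-2.47, adjusted p = 1.2e-05). Immature markers fell (1 higher, 8 lower of 18, median -1.15, 0.000816, adjusted p = 0.0914 with an estimated correlation). Vpreb3 fell from 92.4 ± 11.4 to 16.7 ± 7.15 (-2.47, adjusted p = 3.11e-05). Cd81 fell from 195 ± 28.8 to 69.5 ± 9.94 (-1.49, adjusted p = 0.000259). Cd93 fell from 23.2 ± 2.71 to 3.55 ± 1.48 CPM (-2.70, SE 0.627, adjusted p = 0.00442). Cd24a was at 419 ± 94 against 567 ± 44.9 CPM (adjusted p = 0.101). Klf2 was at 59.7 ± 6.28 against 77.7 ± 25 (0.545).

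The other lists of mouse FO against T3 went both ways. MYC targets fell (4 higher, 19 lower of 60, median -0.86, camera adjusted p = 0.00569, adjusted p = 0.167 with an estimated correlation). Npm1 fell from 535 ± 108 to 179 ± 15.3 CPM (-1.58, adjusted p = 2.48e-05), although Myc itself rose from 55.4 ± 24.7 to 140 ± 42.5 (1.32, adjusted p = 0.0351, and 0.121 with mouse as a block). Tricarboxylic acid cycle genes fell (1 higher, 9 lower of 24, 0.00871, adjusted p = 0.176 with an estimated correlation). Fh1 fell from 74.7 ± 9.19 to 23.4 ± 1.14 CPM (adjusted p = 0.000225). Quiescence factors rose (12 higher, 2 lower of 33, 0.0227, adjusted p = 0.151 with an estimated correlation, and 0.0695 with the length trend removed). Zfp36l1 rose from 186 ± 109 to 999 ± 180 (adjusted p = 0.000113). Foxp1 rose from 220 ± 27.6 to 452 ± 22.8 CPM (1.04, adjusted p = 0.000476, and -0.21, 0.553 with the length trend removed). Monocyte markers fell (4 of 6, 0.0394, adjusted p = 0.181 with an estimated correlation, and 0.343 with the length trend removed). Adenosine genes had 2 higher of 9 (0.351, median -0.17, leaning up). Slc29a3 rose from 8.69 ± 10.9 to 47.4 ± 15.5 CPM (2.38, adjusted p = 0.0281, and 0.0936 with the length trend removed). Adora2a rose from 0 to 24 counts (at least 7.86-fold, adjusted p = 0.00699). Entpd1 was at 15.6 ± 8.31 against 4.7 ± 5.48 CPM (0.229). Ada was at 3.27 ± 1.65 against 4.31 ± 6.99 (0.906). Adk was at 2.27 ± 0.404 against 3.14 ± 4.18 (0.782). Slc29a1 was at 4.78 ± 2.81 against 12.7 ± 8.64 (0.203). Purine salvage had 5 lower of 15 (0.224). Aprt fell from 47.9 ± 16.4 to 13.7 ± 3.37 CPM (-1.81, adjusted p = 0.001, and -1.04, 0.0647 with the length trend removed). De novo synthesis had 1 higher and 5 lower of 13 (0.181). Impdh2 fell from 125 ± 16.4 to 46 ± 7.25 (adjusted p = 0.000305). Mitochondrially encoded genes had 1 higher and 5 lower of 12 (median -0.82, mean 0.15, leaning down, 0.0552), and plasmacytoid dendritic cell markers 0 higher and 3 lower of 6 (0.051, 0.0329 with mouse as a block, and 0.253 with the block and an estimated correlation).

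Among the largest changes against T3 by the naming rule most were again at or near the floor. Zbed6 (160 counts against 0, at least 52.1-fold), Exoc6b (at least 32.7-fold), Slc37a1 (at least 23.3-fold), Mapkbp1 (at least 23.2-fold), Dcdc2c (at least 22.4-fold), Ryr2 (at least 21.6-fold) and Fbxo21 (at least 21.1-fold) were higher in FO. Jchain (at least 16.2-fold) and Cplx2 (at least 12-fold) were lower, as were Rgs13 (from 68.6 ± 20 to 1.04 ± 1.07 CPM, log2 -5.96, adjusted p = 8.17e-05), Mgst1 (ratio 77.5, counting interval 14.2 to 3130), Hbb-bt (72.9, 13.4 to 2940), Prr15 (47.1, 13.3 to 396), Dynlt1-ps1 (40.1, 7.35 to 1620) and Inafm2 (log2 -4.71, adjusted p = 0.00881). The edgeR test called 2542 genes (1106 higher, 1436 lower), 1886 with mouse as a block (1861 shared) and 1676 with the length and GC trend removed (608 higher, 1068 lower, 1322 shared). RLE scaling raised the median by 0.2 on the log2 scale and the higher share from 43.5 to 54.2%.

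Changes from T1/T2 to FO were weakly correlated between human and mouse. Over 7448 genes with a common symbol the log2 fold changes had a Pearson r of 0.205 (jackknife SE 0.0313), with the same sign in 59.6% of genes. With the length and GC trend removed in both species r was 0.125. Among 71 genes called in both species, 64 had the same sign, 13 higher against 5.37 expected if calls were independent and 51 lower against 18.5. With donor as a block in human 470 were called in both, 82 higher in both against 41.1 expected and 323 lower against 118. The expected counts make no allowance for abundance or transcript length, and the overlap was not counted with the trend removed. The 71 rest on the unblocked human calls, which went to 0, 2 and 0 without 1 FO library. For T3 against T1/T2 r was 0.0283 (SE 0.0473). The difference between species was tested in edgeR and passed for 1495 genes (821 higher in human than in mouse, 674 lower, 2510 at an unadjusted p under 0.05). The balance depended on the scaling and the tool, with 557 higher and 872 lower under RLE and 690 and 951 in limma voom. The test was not run with the length and GC trend removed. Log2 fold changes of FO against T1/T2 had a rho with transcript length of 0.51 in mouse and 0.12 in human. A batch of the mouse FO libraries would enter this difference as well. The difference passed for MYC, at -0.25 in human and 2.35 in mouse (log2 difference -2.61, SE 0.615, adjusted p = 0.00516). Mouse Myc was at 14 CPM in T1, 57.4 in T2 and 140 in FO, so the mouse value depends on how T1 and T2 are weighted. The shares of T1 and T2 in the human T1/T2 cells are not known. The difference did not pass for ADK (1.94, SE 0.771, adjusted p = 0.0776), KLF2 (-0.06, 0.956), ENTPD1 (0.29, 0.848), ADORA2A (-0.16, 0.894), SLC29A1 (-0.33, 0.851), ADA (-0.06, 0.981) or CD93 (0.49, 0.783), and NT5E could not be tested. GPR183, which fell in human and rose in mouse, passed as well (log2 difference -4.68, SE 0.346, adjusted p = 1.38e-08), but was picked after the values were seen.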

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

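The test of continued maturation, the test of short abundant transcripts and the regroupings of libraries were written before their results were seen, and the other tests in this part were chosen after the patterns were seen.

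Dixon's ratio at its 95% critical value flagged 6 genes in the mouse FO group. Ryr2 was at 27.9 CPM in FO replicate 2 against 8.4 to 9.46 in the others. The other 5 flags are void, since with 1 count in one library and 0 in the others the ratio is 1 by construction. Of these Mgst1, Hbb-bt and Dynlt1-ps1 were each at 0.845 CPM in FO replicate 2 against 0, Inafm2 was at 0.84 in FO replicate 4 against 0, and Wfdc21 at 0.789 in FO replicate 1 against 0. Chance marks about 1 in 20 groups, and 38 measures were tested. The FO response of MYC differed between human and mouse by a test of the difference itself (log2 -2.61, adjusted p = 0.00516, edgeR). That test weights mouse T1 and T2 equally, while their shares in the human T1/T2 cells are not known.

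Mouse FO libraries stood apart from transitional libraries in 3578 genes, among them lower Uqcrh and Cox4i1, and several technical causes may share in this. With each library's length and GC trend removed, the FO difference was -0.946 for the respiratory chain (pooled SD 0.0689, FO below all T1 and T2 libraries), which argues against that trend as the whole cause, and -0.46 for ribosomal proteins (pooled SD 0.219, FO not below all), where most of the difference went with the trend. The 2 transitional libraries with most ribosomal RNA (64.2 and 61.3%) lay at 0.0198 and 0.291 on an axis from transitional (0) to FO (1). FO lay at 0.9 or more, which for these 2 argues against that share as the whole cause. No transitional one exceeded 0.291. An FO library batch and the change of population cannot be told apart here. Of genes called in FO against T3 with the trend removed, 62.4% kept the sign of T2 against T1. Another regrouping gave 67.5%, so continued maturation and batch are not separated.

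Lower COX7B, UQCRH and RPS24 in human FO may reflect a lower metabolic rate or a technical loss of short transcripts. With the length and GC trend removed, the FO difference was -0.593 for the respiratory chain (pooled SD 0.0627) and -0.613 for ribosomal proteins (pooled SD 0.18), which argues against the trend as the whole cause. Short, abundant transcripts fell in general, since 10000 random lists matched to the respiratory chain on length and expression had medians from -0.383 to -0.00544 (middle value -0.213). The respiratory chain itself was at -0.517, below all of these lists. Ribosomal protein genes were kept out of the random lists. Genes for these lists were drawn singly, without the correlation within a real list. The test therefore cannot decide whether a general fall was the whole cause. The ribosomal part was not tested in this way, so there too a general fall stays open. The share of ribosomal RNA and the number of genes detected also differed between these groups, and their part in the fall was not tested. Transcript shares do not measure respiration, so metabolic rate was not tested.

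S100A9, S100A8 and TYROBP, among the more abundant monocyte markers, had lower estimates in human FO than in T1/T2 libraries. Without the donor block none passed the edgeR test, and against T3 no gene passed. Monocyte RNA in the transitional libraries is a candidate source of the lower monocyte list. Within groups the measured markers had a median pairwise r of 0.673 (random gene sets, 95th percentile 0.134), which fits that source. T cell markers exceeded monocyte markers by a mean log2 difference of 2.37 (SE 0.362 over genes, not libraries). An even rise of all other cells thus stays open. Sort gates, which might have removed monocytes, are not given.

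Regroupings of the same libraries give few alternatives with 3 against 3, where only 10 splits exist, too few for a test. In human T3 against T1/T2, 0 genes were called and the highest other split had 0 (10 of 10 as large), and 7 lists against 9 (2 of 10). In human FO against T3 the values were 0 and 0 genes (10 of 10) and 12 and 13 lists (2 of 10), and in human FO against T1/T2 they were 206 and 0 genes (1 of 10) and 9 and 8 lists (1 of 10). With donor as a block the real splits gave 47, 2 and 1248 genes, and the highest among the 3 other splits parting as many same-numbered pairs was 0 in each. Mouse T2 against T1 had 26 genes against 1 (1 of 10) and 10 lists against 2 (1 of 10), and mouse T3 against T2 had 8 genes against 9 (2 of 10) and 2 lists against 1 (1 of 10).

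More splits exist for the mouse FO comparisons. FO against T3 had 2542 genes, above the highest other split of 304 (1 of 35 as large), but its 8 lists lay below another split's 10 (2 of 35). Among the 7 other splits parting as many same-numbered pairs the highest were 0 genes and 7 lists. FO against T1 and T2 had 3578 genes, above 1140 (1 of 100), while its 9 lists lay below 11 (9 of 100), and both highest values stayed among the 42 splits parting as many pairs. The FO correlation between species, 0.205, lay just above the highest other split at 0.198 (1 of 100), the T3 correlation of 0.0283 was reached by 16 of 100 (highest 0.0503), and the 1495 genes with a species difference exceeded every other split, the highest of which had 1 (1 of 100).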

How the results depend on the processing

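Of 6643 values for 309 genes under the alternatives, 5800 kept direction and call, 515 were weaker, 218 stronger, 105 moved and 5 reversed. Of 3266 values for 198 lists, 2775 kept both, 147 were weaker, 144 stronger, 195 moved and 5 reversed. The length and GC correction, the blocked fits with a donor out, the monocyte covariate, the removal of mouse 2 and the thinning were chosen after seeing the data. Unless the alternative has fewer samples or genes by construction, the cause was not tested.

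DESeq2 called 191, 17 and 1104 genes in human T3 against T1/T2, FO against T3 and FO against T1/T2, and 212 and 159 in mouse T2 against T1 and T3 against T2. Without a low-count filter these were 268, 1.2e+02 (9 higher, 114 lower), 1027, 184 and 162. Limma voom called 62 in mouse T2 against T1. With only the compared groups in the fit, human FO against T1/T2 had 69, mouse T2 against T1 had 2 and T3 against T2 had 0.

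Same-numbered human libraries correlated at 0.125 to 0.562 after group means were removed. The replicate block gave 47, 2 and 1248 genes in human and 4 in mouse T3 against T2, and among the lists and named genes it changed no call beyond the values printed beside the results. With the block and donor 1, 2 or 3 out, human FO against T1/T2 had 42, 381 and 982 genes, T3 against T1/T2 had 0, 1 and 9, and FO against T3 had 0, 0 and 23. With the length and GC correction and the block there were 67, 0 and 1317 genes in human T3 against T1/T2, FO against T3 and FO against T1/T2, and 5, 1055 and 1867 in mouse T3 against T2, FO against T3 and FO against T1 and T2. Without the block the correction gave 1676 in mouse FO against T3. The monocyte covariate left 10 genes in human FO against T1/T2.

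Leaving out 1 library at a time, genes ranged 0 to 0, 0 to 0 and 0 to 264 in the human comparisons in the order above, and 5 to 44, 5 to 15, 1857 to 2269 and 2798 to 4058 in mouse. Lists ranged 5 to 10, 11 to 18 and 9 to 11 in human, and 6 to 11, 1 to 2, 6 to 12 and 8 to 9 in mouse. The correlation between species ranged 0.18 to 0.207 for FO and -0.0032 to 0.0445 for T3, and the species difference 1049 to 1990 genes.

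With an estimated correlation 0, 0 and 1 lists passed in human and 2, 0, 1 and 3 in mouse, and with the block too the human list was lost (0.196). Fry gave 1 and 2 in human T3 against T1/T2 and FO against T3, and 0, 21 and 21 in mouse T3 against T2, FO against T3 and FO against T1 and T2. Mouse T3 against T2 had 1 list without immunoglobulin and mitochondrial genes, 1 without mouse 2 and 4 after thinning to a common depth.

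The FO correlation moved to 0.25 (Spearman), 0.286 (at least 10 CPM), 0.3 (genes called in at least 1 species), 0.125 (length and GC corrected) and 0.135 (with the block too), and the T3 correlation to 0.28 among called genes.

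Reversed in human FO against T3 were handling stress genes (0.0163 with the block and donor 2 out), NK markers (0.809) and monocyte markers (0.652), the last 2 with the monocyte covariate. For monocyte markers the loss of the call follows from the covariate, which was their own mean. In mouse FO against T3 the mitochondrially encoded list turned up with the correction (0.0146, and 0.0101 with the block), and Foxp1 turned to -0.21 and -0.20 (adjusted p = 0.553 and 0.665). In mouse FO against T1 and T2, mt-Nd4 turned to 0.14 and 0.15 (0.633 and 0.636) and Hprt to 0.0271 (0.972 with the block).

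Depth limits the mouse results, since libraries held 0.422 to 1.985 counts (in units of 1e6) outside ribosomal RNA, mitochondrial included, and Nt5e, Mki67 and Mme could not be tested.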

Other observations

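The genes in this part were chosen after the values were seen, and no test beyond the comparisons already given was planned for them. From mouse T1 over T2 and T3 to FO, Ms4a1, which codes for CD20, was at 3692, 1791, 953.1 and 320.9 CPM. It fell from T1 to T2 (adjusted p = 0.0167) and from T3 to FO (log2 -1.57, adjusted p = 2.07e-05), while T3 against T2 did not pass (-0.91, adjusted p = 0.0807). Ighm, the IgM heavy chain, was at 12570, 7219, 4267 and 1969 CPM and fell from T3 to FO (-1.12, adjusted p = 0.000665) and in T3 against the mean of T1 and T2 (-1.16, adjusted p = 0.00561). Ifi30 was at 774.3, 576.3, 194.5 and 40.81 CPM and fell in FO against T1 and T2 (-4.03, adjusted p = 9.66e-10). Opposite to these, Ighd was at 229.1, 624.9, 1126 and 3240 CPM and rose in T3 against the mean of T1 and T2 (1.57, adjusted p = 0.00044).

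Ms4a4c, a relative of Ms4a1, had its highest mean in mouse T3, at 35.4, 81.5, 169.4 and 84.54 CPM from T1 to FO. T3 against T2 did not pass (log2 1.06, adjusted p = 0.161). It rose in T3 against the mean of T1 and T2 (log2 1.65, adjusted p = 0.000896) and fell from T3 to FO (-1.003, adjusted p = 0.00812). In T3 against the mean of T1 and T2 edgeR called 149 genes (69 higher, 80 lower), and 77 with mouse as a block.

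The first principal component held 38.2% of the variance in mouse, with FO libraries at 84.75 to 97.3 and transitional libraries at -55.75 to -8.656, and 35.3% in human, where the T1/T2 libraries spread widest. On the second component in mouse (13.3%) T3 replicate 2 was at -114 and the other libraries at -9.894 to 44.38. Mouse mt-Co3 had 324.7 ± 296 CPM in T1, 0 in T2 and T3, and 78.73 ± 157 in FO, where replicate 3 alone had 314.9. Since mt-Co1 was at 1979 CPM or more in every mouse library, whether mt-Co3 was counted alike in all libraries is unknown, and its values are not read as a change between stages.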
